A study of Orestias ascotanensis with 42 samples.

How the data were processed

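Poly-A RNA libraries of gills, skin and muscle from 14 wild Orestias ascotanensis were sequenced as unstranded 150 bp read pairs, per the labels' protocols. The authors deposited 1 table of raw counts per gene, with 21024 genes in rows and 42 libraries in columns, all of which were used. The submitters' processing notes name FastQC, Trim Galore 0.6.6, HISAT2 2.2.1, Cufflinks and SAMtools 1.10, without their order or role; the genome build, the annotation and the counting program are not given in the sources used here. In the deposited counts, 75.8% of values from 1 to 10 were even, and the value 2 was 20024 times present against 4299 times for the value 1, as happens when both mates of a pair are counted. Scatter between libraries was therefore divided by 2 before it was set against sampling noise. Because the library protocol keeps no strand, overlapping and antisense genes cannot be told apart in these counts, and genes that share reads with near copies are uncertain.

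Groups were taken from the sample titles, which give the tissue, the season and a number from 1 to 7 and match the column names of the table. In 4 libraries (skin summer 7, gills winter 7, gills summer 1 and muscle winter 4) the season tag differs from the title; the titles were followed, and the alternatives were leaving these libraries out or following the tag. The same number within a season marks the same fish across tissues, per the labels. Numbers in different seasons name different fish. Deviations from the group mean correlated at a mean r of 0.199 between gills and skin of the same fish, 0.0711 between gills and muscle and 0.118 between skin and muscle, and a library correlated best with its own fish in 7, 1 and 4 of 14 fish. Each p-value measures the spread between these libraries.

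Analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Seasonal differences within a tissue were tested on its 14 libraries with edgeR's robust quasi-likelihood test (two-sided, TMM scaling, filterByExpr), as summer minus winter. Interactions between season and tissue, and differences between tissues averaged over season, came from 1 fit of all 42 libraries over the 6 groups. Adjusted p-values are edgeR's, after Benjamini and Hochberg, with a threshold of 0.05. Levels are CPM scaled by TMM, within the tissue for season and over all 42 libraries for tissues and interactions, and log2 CPM used a prior count of 2. Shares of counts were compared between seasons by exact permutation over 3432 splits. Tissue-enriched groups, defined after seeing the data, hold genes at least 2 higher on the log2 scale than in both other tissues in the fit over all libraries, and their seasonal shift was tested with camera.

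Named genes were picked by a rule set before the data were examined: among genes past the threshold with an average log2 CPM of at least 1 and at least 6 of 7 summer libraries beyond the winter median, the largest increases and decreases. For interactions the rule took genes with an average log2 CPM of at least 1 and the smallest p, here the first in each direction, and for tissue identity genes with a mean log2 CPM of at least 5 in their tissue and the largest fold over the closer of the other tissues. The files do not pair identifiers with names, so at most 2 identifiers that rose and 2 that fell are printed per comparison. For the same reason the gene lists and cell type markers fixed before the data were examined could not be matched to any gene, and every test of them is void.

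Before the tests were run on the deposited counts they were tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold. In the season test the simulation recovered 89 and 94 of them in gills, 34 and 88 in skin and 40 and 97 in muscle. In the interaction of gills with skin it recovered 31 and 92, of gills with muscle 27 and 90, and of skin with muscle 31 and 87. Tissue differences recovered 83 and 99, 92 and 98, and 83 and 98 for the same pairs. Among the unchanged genes the season test called 13 in gills, 5 in skin and 8 in muscle. The changed genes were drawn from well-counted genes only. Each library was drawn independently, without the closeness between some libraries described below. These shares therefore do not give the power of the tests on the deposited counts. A pair of simulated draws from 1 library had a MAD of 0.0532.

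Libraries of a group were compared in pairs by the MAD of the log2 count ratio. Those under 0.15 were called near-identical, and libraries whose median correlation with their tissue was under 0.88 (skin summer 3, skin summer 4 and muscle summer 4, at 0.866, 0.840 and 0.790) were said to stand apart. Both limits were set after seeing the data. Alternatives planned before the data were examined were RLE scaling, no filter on low counts, DESeq2, limma voom, edgeR without robust estimation, blocks for the individual number or the fish, both treatments of the conflicting season tags, 1 fit of all libraries, and leaving out each library in turn. Averaging near-identical libraries, leaving out those that stand apart, quality weights and the choices of 4 summer muscle libraries were added after seeing the data. Real groupings were set against 100 assignments of whole fish to seasons, or 40 swaps of tissue labels within fish, the real one included. The averaged samples of each tissue were also split 100 times, the real split included, an analysis added after seeing the data. Averaging scaled each set's counts to its mean total and rounded them.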

Results

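Gene expression was measured by poly-A RNA sequencing in the gills, skin and muscle of Orestias ascotanensis, a killifish of the Ascotán salt pan at 3740 m in the high Andes of Chile. The fish were wild: 7 were sampled in the southern winter of 2019 and 7 in the southern summer of 2020, and each fish gave 1 library per tissue. The 42 libraries therefore formed 6 groups of 7, with 14 fish in all. Each season was sampled in a single year. Differences called seasonal here therefore cannot be told apart from differences between the years or the collections. The deposited table held raw counts for 21024 genes, of which 143 had no count in any library. Total counts per library ranged from 6074371 in muscle summer 4 to 154396513 in muscle summer 5. The next lowest total was 28009075, in muscle summer 6. In muscle summer 4, 30.3% of the genes were at 0. Genes are given by the identifiers of the table, since the files do not pair them with gene names.

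The first question was how far the tissues differed from each other. Principal component analysis of log2 CPM (counts scaled to a common library total) separated the 3 tissues: the first component held 55.5% of the variance and the second 13.5%. Averaged over the seasons, 12262 of 19258 genes differed between gills and skin, 15629 between gills and muscle and 13671 between skin and muscle, at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 6538 were higher in skin than in gills, 8331 higher in gills than in muscle and 7331 higher in skin than in muscle. The genes most specific to each tissue differed by orders of magnitude. In gills, OAV3G000007811 averaged 223 ± 28.4 CPM (SD, n = 14), against 1.35 ± 2.50 in skin and 2.72 ± 6.44 in muscle. OAV3G000020896 averaged 35.6 ± 7.44 CPM in gills, 0.282 ± 0.515 in skin and 0.685 ± 1.74 in muscle. In skin, OAV3G000002407 reached 45.0 ± 17.6 CPM while gills held 0.175 ± 0.166 and muscle 0.173 ± 0.296. OAV3G000011885 averaged 68.8 ± 54.0 CPM in skin, 0.546 ± 0.619 in gills and 1.21 ± 2.097 in muscle. In muscle, OAV3G000004951 averaged 45.6 ± 23.2 CPM, against 0.405 ± 0.284 in gills and 0.239 ± 0.184 in skin. OAV3G000015893 averaged 74.0 ± 23.3 CPM in muscle, 0.163 ± 0.1003 in gills and 1.05 ± 0.584 in skin.

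**Figure D1:**
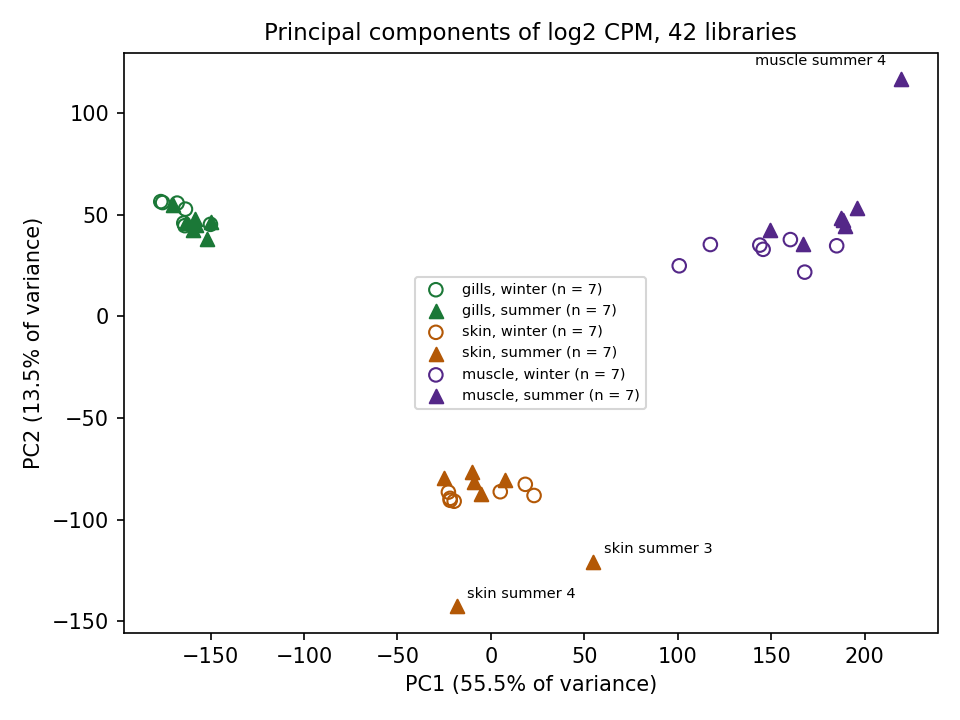
First principal component (55.5% of variance) against the second (13.5%) for log2 CPM of the 42 libraries; colour marks the tissue, open circles winter and filled triangles summer. The 3 tissues form separate clusters, and skin summer 3, skin summer 4 and muscle summer 4 lie away from the rest of their tissue.

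Genes with at least 4-fold higher levels in 1 tissue than in both others formed 3 tissue-enriched groups, of 791 genes for gills, 224 for skin and 1107 for muscle. The groups were defined from these same libraries. Muscle-enriched genes took 66.2% ± 4.34 (SD, n = 7) of the counts of winter muscle and 63.5% ± 3.07 of summer muscle. They also took 21.1% ± 4.52 of the counts of winter skin and 25.7% ± 7.84 of summer skin, a difference within the spread between fish (two-sided exact permutation p = 0.204, adjusted p = 0.628 over 9 comparisons). In gills their share was 1.11% ± 0.518 in winter and 1.32% ± 0.301 in summer (exact permutation p = 0.375). Gill-enriched genes took 6.14% ± 0.177 of the counts of winter gills and 6.20% ± 0.592 of summer gills (exact permutation p = 0.828).

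Libraries of one group did not all differ from each other by the amount usual between fish. The robust spread of the log2 count ratio between a pair of libraries (median absolute deviation, MAD, over genes with at least 1000 counts in the pair) was under 0.15 in 12 of the 126 pairs within groups. In the other pairs it ran from 0.160 to 1.68. Between seasons it was under 0.15 in 2 pairs, of gills summer 1 with gills winter 2 (0.139) and with gills winter 7 (0.140); gills summer 1 and gills winter 7 are among the libraries whose season tag differs from the title. These 2 pairs were not averaged. The close pairs formed 5 sets: gills winter 2 and 7, gills winter 3 and 6, gills summer 4 and 7, skin winter 2, 6 and 7, and muscle summer 3, 5, 6 and 7. Their MAD ranged from 0.0746 to 0.144. Among genes with 20 to 160 counts in the pair, the median scatter of these pairs was 1.14 times sampling noise in gills, 1.86 in skin and 1.41 in muscle, against 3.46, 5.82 and 4.34 in the other pairs. Each library was kept as a sample, as planned; these values do not settle whether the libraries of a set are separate samples. The seasonal and interaction counts of genes past the threshold are also given below with each set averaged into 1 sample, which leaves 5 winter and 6 summer samples in gills, 5 and 7 in skin, and 7 and 4 in muscle.

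**Figure D2:**
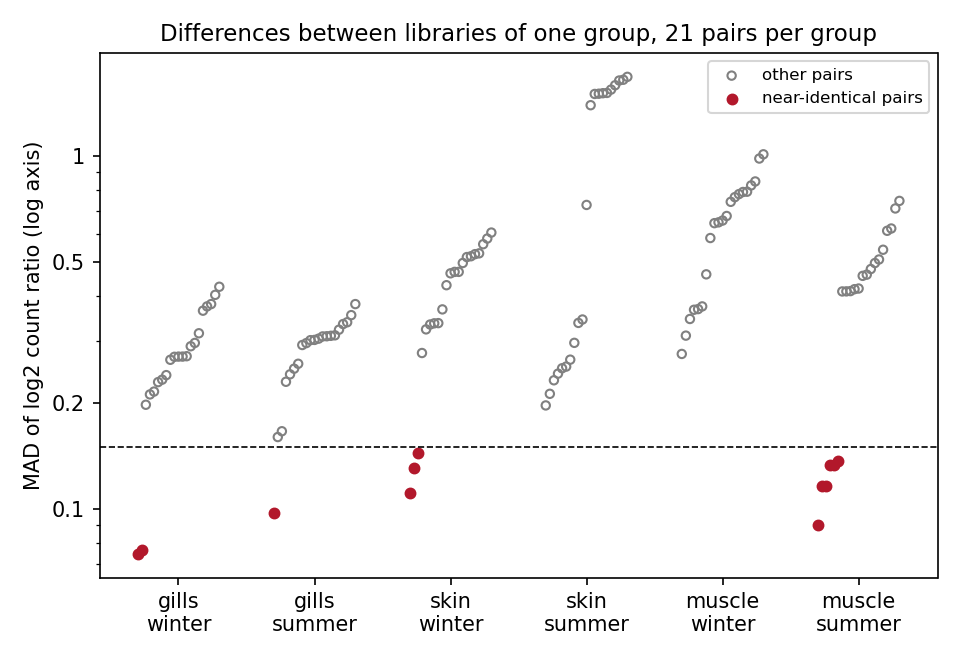
MAD of the log2 count ratio (log axis) for every pair of libraries within each tissue and season. Filled points are the near-identical pairs, all under the dashed line at 0.15; open points are the other pairs, which start at 0.160.

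The comparison of summer with winter gills asked which genes of the tissue that exchanges gas and salts with the water differed between the seasons. No gene of 18409 passed an adjusted p of 0.05 in edgeR. The gene with the smallest p, OAV3G000018138 (chosen after its values were seen), averaged 25.7 ± 2.32 CPM in summer against 35.7 ± 3.52 in winter (SD, n = 7). Its log2 fold change was -0.48 ± 0.08 (SE), all 7 summer libraries lay below the winter median, and its adjusted p was 0.0973. It passed in DESeq2 (adjusted p = 0.000167), in limma voom with quality weights (0.0178) and in edgeR without gills summer 2 (0.0468). In 22 of 25 alternatives it missed the threshold. An unadjusted p under 0.05 was found for 2669 genes, where 920 would be expected with no difference; 1119 of them were higher and 1550 lower in summer. Gill-enriched genes had a median log2 fold change of 0.06, skin-enriched genes 0.14 and muscle-enriched genes 0.15 in gills. All 3 groups passed camera with its preset correlation, and none did with an estimated correlation (adjusted p = 0.351 for each). On the same libraries DESeq2 called 398 genes, limma voom 0, and limma voom with quality weights, an alternative chosen after seeing the data, 717. With the near-identical libraries averaged edgeR called 0 genes and gave 1495 with p under 0.05; without gills summer 2 it called 135. In 1 fit over all 42 libraries no gene passed, and 272 of 19258 genes had an unadjusted p under 0.05, where 963 would be expected.

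The same comparison in skin also gave no gene past the threshold, of 18260 tested. OAV3G000020083 had the smallest p (chosen after its values were seen). It averaged 35.1 ± 25.8 CPM in summer against 9.60 ± 0.639 in winter (SD, n = 7), a log2 fold change of 1.87 ± 0.33 (SE) with an adjusted p of 0.331, and was above the winter median in 7 of 7 summer libraries. Skin summer 3, which stands apart from the other skin libraries, held the highest level at 89.9 CPM. Without skin summer 3 and skin summer 4 the log2 fold change was 1.197 with an adjusted p of 3.83e-05, and 1.21 with 0.000747 when near-identical libraries were averaged as well. The adjusted p was also under 0.05 with quality weights (log2 fold change 1.19, 5.75e-06) and in 1 fit over all 42 libraries (1.88, 0.000107). Of 2064 genes with an unadjusted p under 0.05, where 913 would be expected, 1682 were higher and 382 lower in summer. There were 1028 such genes without skin summer 3, 1524 without skin summer 4 and 2006 without both. Skin-enriched genes had a median log2 fold change of 0.36, gill-enriched genes 0.26 and muscle-enriched genes 0.13; their camera calls with the preset correlation were lost with an estimated one (adjusted p = 0.351, 0.351 and 0.483). Without skin summer 3 and skin summer 4 the median of skin-enriched genes was -0.01. DESeq2 called 78 genes, limma voom 0, limma voom with quality weights 3537 (1802 higher and 1735 lower) and 1 fit over all 42 libraries 289. With near-identical libraries averaged edgeR called 0 genes and gave 1391 with p under 0.05, and without the libraries that stand apart it called 2.

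In muscle, 1100 of 17181 genes passed the threshold: 406 were higher and 694 lower in summer, and 495 changed at least 2-fold (189 up and 306 down). The gene with the smallest p, chosen after its values were seen, is given without its identifier because the 2 printed risers are others. It averaged 49.6 ± 12.8 CPM in summer against 16.6 ± 3.43 in winter (SD, n = 7). Its log2 fold change was 1.58 ± 0.20 (SE) with an adjusted p of 0.00438, and all 7 summer libraries lay above the winter median. Of the genes that the naming rule picked as largest risers, OAV3G000018214 went from 0.0673 ± 0.158 CPM in winter to 27.2 ± 67.8 in summer (SD, n = 7), with a log2 fold change of 8.76 ± 2.12 (SE) and an adjusted p of 0.0300. OAV3G000009956 went from 0.0812 ± 0.125 to 17.0 ± 41.7 CPM (log2 fold change 7.91 ± 1.94, adjusted p = 0.0306). Both means were set by muscle summer 4, at 181 and 112 CPM; without it the log2 fold changes were 4.65 and 4.15, with adjusted p of 0.0259 and 0.0264. In limma voom on all libraries they were 5.21 and 4.62 with adjusted p of 0.121 and 0.0823, and in DESeq2 3.91 and 3.87 with 0.103 and 0.0189. The winter mean of OAV3G000018214 was set by muscle winter 3, at 0.424 CPM; without it the log2 fold change was 12.33. OAV3G000018214 missed the threshold without muscle winter 1, 2, 5, 6 or 7 (adjusted p from 0.0502 to 0.0733). OAV3G000009956 missed it without any 1 of the same libraries or muscle summer 7 (adjusted p from 0.0523 to 0.0766). Summer lay above the winter median in 6 of 7 libraries for the first gene and in 7 of 7 for the second. Among genes that met the naming rule in this fit of muscle alone, the largest decreases were in OAV3G000004466 and OAV3G000019271. OAV3G000004466 went from 6.02 ± 9.74 to 0.167 ± 0.101 CPM (log2 fold change -5.02 ± 1.198, adjusted p = 0.0260). OAV3G000019271 went from 14.0 ± 20.6 to 0.459 ± 0.342 CPM (-4.75 ± 0.93, adjusted p = 0.0125). All 7 summer libraries lay below the winter median for both. Few winter libraries carried these means: OAV3G000004466 was at 25.9, 11.9 and 3.51 CPM in muscle winter 5, 7 and 6 and at 0.345 or less in the other 4, and OAV3G000019271 was at 57.1, 22.5 and 11.1 CPM in muscle winter 2, 6 and 4 and at 2.57 or less in the rest. Without muscle winter 5 the log2 fold change of OAV3G000004466 was -3.85 (adjusted p = 0.0318), and without muscle winter 2 that of OAV3G000019271 was -3.71 (adjusted p = 0.0189). In limma voom neither passed (OAV3G000004466 -2.64, adjusted p = 0.233; OAV3G000019271 -3.49, adjusted p = 0.0919). OAV3G000004466 also missed the threshold without muscle summer 3, 5, 6 or 7 (adjusted p from 0.0540 to 0.0612). With the season taken from the tag, which moves muscle winter 4, OAV3G000019271 had -2.92 (adjusted p = 0.138), and OAV3G000018214 and OAV3G000009956 had adjusted p of 0.0646 and 0.0692.

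Among gill-enriched genes, 373 were tested in muscle: 1 rose, 54 fell and 318 did not pass, with a median log2 fold change of -0.40. These genes took 0.0989% ± 0.0566 of the counts of winter muscle and 0.0668% ± 0.0248 of summer muscle (SD, n = 7; exact permutation p = 0.209). Of 129 skin-enriched genes, 9 rose, 3 fell and 117 did not pass (median 0.18). Of 1056 muscle-enriched genes, 39 rose, 22 fell and 995 did not pass (median 0.21). The adjusted camera p was 9.79e-06, 0.0124 and 0.00111 with the preset correlation, and 0.351 for each group with an estimated correlation.

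The muscle count changed with how the near-identical summer libraries were counted. With muscle summer 3, 5, 6 and 7 averaged into 1 sample, edgeR called 0 genes, while 2789 had an unadjusted p under 0.05 against 4163 with all libraries. Averaging also leaves fewer summer samples, which alone may lower the count. All 1100 genes called with every library kept their sign in these averaged data. Their median absolute log2 fold change was 0.932, against 0.948 before averaging. These genes were picked for their difference in the same libraries. Kept signs and sizes were therefore largely given in advance and do not tell whether the calls hold. The named genes had log2 fold changes of 9.50 (OAV3G000018214), 8.64 (OAV3G000009956), -5.18 (OAV3G000004466) and -4.56 (OAV3G000019271), with adjusted p from 0.143 to 0.221. In all 35 choices of 4 of the 7 summer libraries against the 7 winter libraries, the choice of the 4 near-identical libraries called 1423 genes, choices with 3 of them 91 to 528, with 2 of them 0 to 4, and with 1 of them 0. With 1 library left out of the 14, the count fell to 472 without muscle winter 2, 457 without winter 6, 644 without winter 7, and 453, 448, 447 and 430 without summer 3, 5, 6 and 7. DESeq2 called 2306 genes, limma voom with quality weights 5112, and 1 fit over all 42 libraries 2896.

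**Figure D3:**
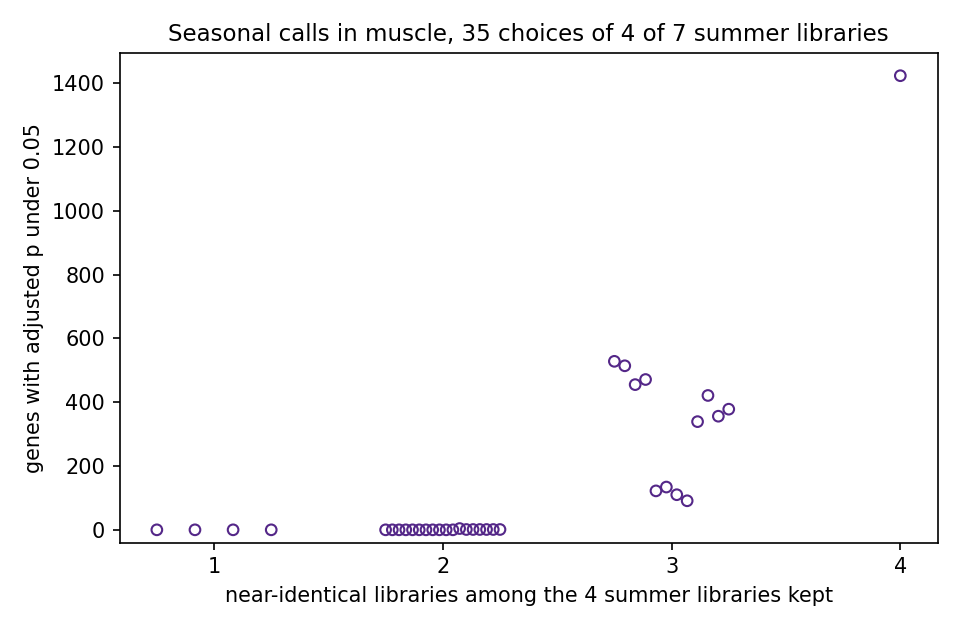
Genes past an adjusted p of 0.05 between summer and winter muscle in edgeR, for each of the 35 choices of 4 summer libraries, by how many of the near-identical libraries the choice holds. Each point is 1 choice; counts are at most 4 with 1 or 2 of them and reach 1423 with all 4.

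Whether the seasonal difference itself differed between tissues was tested as an interaction in 1 fit of the 42 libraries, and levels here are scaled over all 42 and so differ from the levels scaled within a tissue above. Between gills and muscle, 445 of 19258 genes passed, 396 with the higher summer minus winter value in gills. OAV3G000008776 fell in muscle from 190 ± 60.0 to 69.4 ± 18.7 CPM (SD, n = 7) and was at 44.4 ± 2.37 and 44.3 ± 3.88 in gills, a log2 difference of 1.45 ± 0.22 (SE; adjusted p = 0.000704). OAV3G000000633 had a log2 difference of 3.05 ± 0.48 (adjusted p = 0.000704), from 0.910 ± 0.580 to 0.139 ± 0.139 CPM in muscle and from 7.84 ± 2.21 to 9.63 ± 1.26 in gills. In the opposite direction, OAV3G000002441 rose in muscle from 21.1 ± 5.69 to 47.4 ± 13.5 CPM, with all 7 summer libraries above the winter median, and was at 15.9 ± 2.86 and 15.5 ± 2.91 CPM in gills (log2 difference -1.19 ± 0.22, adjusted p = 0.00288). OAV3G000011140 had a log2 difference of -5.88 ± 1.24 (adjusted p = 0.00694), and its summer muscle mean of 40.5 ± 99.9 CPM was set by 1 library at 267. Without the libraries that stand apart it had -2.09 with an adjusted p of 0.0660, and in DESeq2 -1.93 with 0.0900, both short of the threshold. With the fish as a replicate block it missed the threshold too. With near-identical libraries averaged the gills against muscle count was 0. DESeq2 gave 920, and leaving out the libraries that stand apart gave 1453. Without the libraries whose season tag differs from the title it was 273.

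Between skin and muscle 931 genes passed, 838 with the higher summer minus winter value in skin. OAV3G000003139, at 362 ± 49.8 CPM in winter gills, went from 7.28 ± 11.1 to 0.0413 ± 0.0430 CPM in muscle and from 1.17 ± 0.891 to 4.52 ± 5.07 in skin (SD, n = 7; log2 difference 8.85 ± 1.27, adjusted p = 0.000177). OAV3G000015415, at 251 ± 48.0 CPM in winter gills, went from 7.22 ± 11.8 to 0.120 ± 0.240 CPM in muscle and from 0.201 ± 0.222 to 2.89 ± 3.78 in skin (log2 difference 9.49 ± 1.38, adjusted p = 0.000177). Single libraries carried these means: the highest winter muscle value was 30.5 CPM for OAV3G000003139 and 32.3 for OAV3G000015415, and the highest summer skin value 15.5 (next 5.21) and 11.2 (next 2.82). In summer muscle OAV3G000015415 was at 0.659 CPM in 1 library and at 0.0789 or less in the others. OAV3G000002441 had a log2 difference of -1.16 ± 0.22 here (adjusted p = 0.00205), with skin at 14.8 ± 1.24 and 14.7 ± 0.779 CPM; it did not pass with near-identical libraries averaged (-1.07, adjusted p = 0.0664). OAV3G000008647 had -6.29 ± 1.28 (adjusted p = 0.00322), with a summer muscle mean of 9.77 ± 23.9 CPM and 1 library at 64.1. It had -2.90 without the libraries that stand apart (adjusted p = 0.0152), -2.63 in DESeq2 (0.00651) and -2.07 with near-identical libraries averaged as well (0.235). With near-identical libraries averaged 54 genes passed, DESeq2 gave 1591, and 1588 passed without the libraries that stand apart. Between gills and skin no gene passed in edgeR, 728 had an unadjusted p under 0.05, where 963 would be expected, and DESeq2 called 3. With near-identical libraries averaged no gene passed there and 306 had an unadjusted p under 0.05.

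The last comparison set the seasonal fold changes of the tissues against each other, across genes, which are not independent replicates. Pearson's r was 0.409 between gills and skin, 0.1999 between gills and muscle and 0.221 between skin and muscle. Because the tissues came from the same fish, whole fish were reassigned to seasons, and the median r of these reassignments was 0.176, 0.0725 and 0.143. An r as large as the real one came from 2 of 100 assignments, the real one included, for gills and skin, 9 for gills and muscle and 28 for skin and muscle. The covariance, which was not among the planned measures, was 0.0453, 0.0284 and 0.0611, against medians of 0.0114, 0.00589 and 0.0215. A covariance as large came from 3, 4 and 4 of 100 assignments. It also grows with the size of the fold changes in either tissue, so it does not by itself show a shared direction. Between gills and skin the r was 0.432 with near-identical libraries averaged, 0.125 without the libraries that stand apart and 0.174 with both choices. Of 16599 genes tested in every tissue, 122 had an unadjusted p under 0.05 and a higher level in summer in all 3 tissues, and 32 a lower one. With near-identical libraries averaged these were 40 and 2 of 17032 genes.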

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

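All tests of explanations in this part were chosen after the results were seen. The near-identical libraries were the first pattern weighed. Fish that were near-identical in every tissue would be under the same limit in the other tissues, but only 2 of 24 such combinations were, where 2.29 would be expected by chance; both are the pair of winter fish 2 and 7, in gills and skin. Fish more alike than others, without reaching that limit, stay open: in the other tissues the pairs of the winter sets had a median rank of 4.5 among 21 pairs, from the closest, and none ranked beyond 7. For the summer sets the ranks ran from 4 to 21 with a median of 13.5, which does not tell. High depth does not account for them either, since 108 other pairs were at least as deep as the shallowest close pair and differed by a MAD over 0.15. A single RNA sample or library behind each set would scatter by about the sampling noise. Among genes with 20 to 160 counts in the pair, the median was 1.14 times the noise in gills, 1.86 in skin and 1.41 in muscle. The gills value is close to the noise, but these genes have few counts. Over all genes, the chi-square of gills winter 2 and 7 was 89088.7 on 18381 degrees of freedom. For gills winter 3 and 6 it was 87246.4 on 18238, and for gills summer 4 and 7 132331 on 18310. Each exceeds its degrees of freedom even when divided by 2 for counted mates. The question stays open in every tissue, because extra scatter from library preparation is unknown. No biological explanation limited to 1 tissue was tested.

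The number of genes called in muscle was the second pattern. It may come from counting the 4 near-identical summer libraries as separate fish: choices of 4 summer libraries that held at most 2 of them called at most 4 genes. The loss of libraries alone stays open: just these 4 summer libraries called 1423 genes, but they spread less than other fish, so this does not tell what 4 ordinary fish would give. The shallow library muscle summer 4 is argued against by the 1523 called without it. These tests do not tell whether the 4 libraries are 1 sample or 4 fish that were alike in muscle. A seasonal difference in muscle stays among the open explanations and was not tested apart from these.

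The libraries that stand apart were the third pattern. Low depth is argued against as the whole cause: other libraries thinned to the same totals kept median correlations of at least 0.874 for muscle summer 4 (itself 0.790), 0.949 for skin summer 3 (0.866) and 0.948 for skin summer 4 (0.840). A larger share of muscle in the piece of skin is consistent with skin summer 3, where muscle-enriched genes took 39.4% of the counts against 15.1% to 30.5% in the 12 other skin libraries. In skin summer 4 they took 16.1%, within that range. Among libraries thinned to the total of muscle summer 4, at most 21.5% of genes were at 0, against 30.3% in muscle summer 4. Low depth may still be a part of the cause in each of the libraries that stand apart. No biological explanation was tested.

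Of 60 groups of 7 libraries examined for 1 value far from the rest, 14 were picked out, and chance picks about 1 in 20, or 3. Muscle summer 4 had 30.3% of genes at 0, a TMM factor of 1.23, a median correlation with its tissue of 0.790 and 0.120% of counts in gill-enriched genes. In skin summer 3 the top gene took 8.58% of counts and the TMM factor was 0.580. The top gene took 1.91% of counts in gills summer 3. Gills summer 1 had the highest median correlation of its group with the other gills libraries, 0.984. Muscle-enriched genes took 2.23% of counts in gills winter 4. Among the named genes, OAV3G000020083 was at 89.9 CPM in skin summer 3. OAV3G000018214 was at 181 CPM in muscle summer 4 and at 0.424 CPM in muscle winter 3. OAV3G000009956 was at 112 CPM in muscle summer 4, and OAV3G000019271 at 57.1 CPM in muscle winter 2.

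Seasonal effects that differed between tissues by the interaction test numbered 445 genes for gills against muscle and 931 for skin against muscle. With near-identical libraries averaged these counts were 0 and 54. The named ones for gills against muscle had log2 differences of 1.45 (OAV3G000008776), 3.05 (OAV3G000000633), -1.19 (OAV3G000002441) and -5.88 (OAV3G000011140). For skin against muscle they were 8.85 (OAV3G000003139), 9.49 (OAV3G000015415), -1.16 (OAV3G000002441) and -6.29 (OAV3G000008647). The seasonal change of OAV3G000020083 differed between skin and muscle with an adjusted p of 0.0227. In the edgeR fits of single tissues its log2 fold change was 1.87 in skin and 0.60 in muscle. Neither passed (adjusted p = 0.331 and 0.144), and skin summer 3 held its highest skin level, at 89.9 CPM. Skin against muscle also gave 0.00462 for OAV3G000018214, 0.0122 for OAV3G000009956 and 0.00130 for OAV3G000019271. Gills against muscle gave 0.00288 for OAV3G000019271. OAV3G000018214 and OAV3G000009956 did not pass the filter on low counts in the season tests of gills and skin. Their summer muscle means were set by muscle summer 4, and these 2 differences were not tested without that library. Within muscle alone both genes still passed in edgeR without it, at smaller log2 fold changes of 4.65 and 4.15 (adjusted p = 0.0259 and 0.0264).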

How the results depend on the processing

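Averaging near-identical libraries, leaving out libraries that stand apart, and quality weights were chosen after seeing the data; the other alternatives were planned. The 3 tissue counts stayed within 1.5 times under every alternative run. Under DESeq2 the seasonal counts were 398 in gills, 78 in skin and 2306 in muscle, and the interaction counts 3 for gills and skin, 920 for gills and muscle and 1591 for skin and muscle. Quality weights gave 717, 3537 and 5112 genes in gills, skin and muscle. A fit of all 42 libraries gave 289 in skin and 2896 in muscle. Averaging gave 0 in muscle, 0 for gills and muscle and 54 for skin and muscle. Leaving out the libraries that stand apart gave 2 in skin, 1453 for gills and muscle and 1588 for skin and muscle, and both together gave 1 in skin, 0 in muscle, 6 and 44. Leaving out the 4 libraries with a conflicting season tag gave 273 for gills and muscle. With 1 library left out, counts ranged from 0 to 135 in gills and from 430 to 1523 in muscle, and stayed at 0 in skin. The cause of these changes was not tested.

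The individual number as a replicate block gave 722 genes in muscle and 0 in gills and skin, where 994 genes of skin had p under 0.05. The number is only shared between seasons: a library correlated best with its own number in 0, 1 and 1 of 7 cases in gills, skin and muscle. With the fish as a replicate block the interaction counts were 0, 404 and 713, and the tissue counts 12570 (gills and skin), 15739 (gills and muscle) and 13688 (skin and muscle), which moved no other count by over 1.5 times. The log2 difference with this block was -2.79 for OAV3G000011140 (adjusted p = 0.136) and -3.72 for OAV3G000008647.

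The correlation of fold changes between gills and skin was 0.569 over genes with an average log2 CPM of at least 3, 0.125 without the libraries that stand apart and 0.174 with near-identical libraries averaged as well. Between gills and muscle it was 0.309 over those genes, 0.116 with libraries averaged and 0.0675 with both. Between skin and muscle it was -0.0498 with both. The cause was not tested. The muscle genes named by identifier missed the threshold in 32 alternatives and passed in 76, always with the same sign. The muscle gene with the smallest p, left out of that tally, passed in 25 of 27 alternatives. It missed the threshold with near-identical libraries averaged (log2 fold change 1.53, adjusted p = 0.143). Planned tests of gene lists were not run, since no identifier is paired with a name. Depth limits muscle summer 4 most, at 6074371 counts.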

Other observations

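The tests in this part were chosen after the results were seen, except the reassignment of fish to seasons for the correlations, which was planned before the data were examined. For the splits of averaged samples within single tissues and for the interactions, what each outcome would mean was written before they were run. The reading for the interactions was changed afterwards, and that for the shared genes was written afterwards. Distances between the 7 winter fish correlated between gills and skin (Mantel r = 0.622, one-sided exact p = 0.0143, adjusted p = 0.0429 over 6 comparisons), between gills and muscle (r = 0.614, exact p = 0.0135, adjusted p = 0.0429) and between skin and muscle (r = 0.723, exact p = 0.0341, adjusted p = 0.0683), the last above the threshold of 0.05. Near-identical pairs, such as winter fish 2 and 7 in gills and in skin, enter these distances. In summer the values were -0.0778 (exact p = 0.487), -0.0281 (exact p = 0.573) and 0.316 (exact p = 0.198). The difference between the seasons was not tested.

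Beyond the near-identical sets, 4 libraries lay close to a weighted sum of other libraries of their tissue: gills summer 1, gills winter 5, skin summer 1 and muscle winter 6. Weights were fitted on alternate genes and the residual taken on the rest. Some of the larger weights fell on the other season. Gills winter 5 drew on gills summer 4, gills summer 1 on gills winter 2 and 7, and skin summer 1 on skin winter 4 and 1. Each of them also drew on its own season, and the larger weights of muscle winter 6 were all on winter libraries. The residual MAD was 0.0547, 0.0806, 0.0900 and 0.133, against 0.121, 0.162, 0.198 and 0.315 to the closest single library, a ratio of 0.452, 0.498, 0.455 and 0.422. The other 25 libraries outside the sets had ratios of 0.540 to 1.26. Material mixed from other fish may give this, but so would a fish whose expression lies between those of others. Mixtures made from a pair of libraries in simulation left residuals of 0.0257 to 0.0273, under those of all 4 libraries. These mixtures were drawn without counting both mates of a pair, which may make their residuals too small. The count of 4 therefore leaves the question open.

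Whole fish were reassigned to seasons 100 times, the real grouping included, with every library counted as a separate fish. For muscle, 1 of 100, the real grouping, gave 1100 genes and the highest of the others 315, and its 4163 genes with p under 0.05 were also reached by 1 of 100 (highest other 3867). The 2669 genes of gills and 2064 of skin with p under 0.05 were reached by 6 of 100 (highest other 3474) and 16 of 100 (highest other 3741), so chance cannot be excluded. The interaction counts of 445 and 931 were reached by 1 of 100 each (highest other 268 and 440). The 154 genes with p under 0.05 and 1 direction in all 3 tissues were reached by 1 of 100 (highest other 122). The real grouping keeps each near-identical set on 1 side, while other assignments can split it, which can favour the real grouping. The shares for muscle, the interactions and the shared genes therefore do not exclude chance. The r of 0.409 between gills and skin was reached by 2 of 100 (highest other 0.410), 0.1999 between gills and muscle by 9 (highest other 0.275) and 0.221 between skin and muscle by 28 (highest other 0.436). A real count of 0 is reached by every grouping, so for the genes called in gills and skin (100 of 100, highest other 185 and 1) and for their interaction (100 of 100, highest other 2) the reassignment tells nothing.

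The averaged samples of each tissue were split 100 times too, with the group sizes kept and the tissues split separately. The 2789 genes with p under 0.05 in muscle were reached by 6 of 100 (highest other 6567), the 1495 of gills by 25 (highest other 2976) and the 1391 of skin by 18 (highest other 5466). For the interactions, 306 genes with p under 0.05 between gills and skin were reached by 62 (highest other 3433), 2110 between gills and muscle by 9 (highest other 6136) and 3199 between skin and muscle by 9 (highest other 6008). The 54 genes past the threshold between skin and muscle were reached by 15 (highest other 2743). Chance can therefore not be excluded for the seasonal counts of the single tissues once near-identical libraries are averaged. Under the reading written beforehand, a share of at least 0.05 would count for chance, and the interactions met it. That reading was dropped afterwards, because these splits break the link between tissues of a fish. The link cancels in an interaction, so the splits may spread more than whole fish would and cannot tell. The 42 averaged genes with 1 direction in all 3 tissues were reached by 1 of 100 (highest other 41), but without that link tissues share fewer genes by chance, so this does not exclude chance. The correlations were not set against averaged splits. Of 40 swaps of tissue labels within fish, only the real labels gave 12262, 15629 and 13671 genes. A share of 1 of 40 each is under 0.05, and is the smallest that 40 labelings can give. The highest others were 7263 for gills and skin, 13557 for gills and muscle and 10788 for skin and muscle, the last 2 from swaps of 2 fish.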
